A study of Mus musculus with 12 samples.

How the data were processed

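Type 1 conventional dendritic cells (cDC1), the dendritic cells specialised in presenting captured antigen to CD8 T cells, were sorted from spleen and from skin-draining lymph nodes of unimmunised C57BL/6 mice, and their RNA was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays (the array type is per the file headers of the probe annotation). All mice carried a Cd40 gene flanked by loxP sites on both alleles. Mice called Cre here also carried 1 Xcr1-Cre allele, meant to delete Cd40 in cDC1, and mice called control carried none. The labels give 4 groups of 3 arrays: spleen control, spleen Cre, lymph node control and lymph node Cre. Per the labels' protocols, cells were negative for B220 and Sirpa, positive for XCR1 and high for MHC class II, with high CD11c in spleen and intermediate CD11c for the migratory cells of the lymph node. Biotinylated cDNA was made with the WT Pico kit from very small amounts of RNA, per the labels' protocols.

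The deposited values are intensities, 1 per probe set and array. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no versions. The values lay between 8.23 and 20398, with medians of 66.1 to 74.4 per array, so they were read as intensities on the linear scale, and log2 was taken before any test. The number of arrays limits the precision. The highest of the 3 measured Y-linked genes, which should be silent in female cells, gave a background of 22.2 in intensity, and 85.8% to 90.3% of the genes on each array lay above it. All 12 arrays had Xist between 2522 and 3721, so sex was not used as a covariate.

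The deposited data held 28853 probe sets. The annotation listed 23410 of them, and 5443 were not listed. Of the listed ones, 21789 carried a single symbol and 1621 carried several and were not tested; 21698 of the single symbols were matched to RefSeq gene names by Entrez number. Where a gene had more than 1 probe set (999 genes), the brightest was kept, which left 19938 genes. No genome sequence was used, so the positions of the Cd40 probes in the gene are not known here, and they may lie outside the deleted exons.

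Each gene was fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 4 group means over the 12 arrays, eBayes with a trend in the mean level, two-sided tests and Benjamini-Hochberg adjustment within each of 6 comparisons. A gene was called at an adjusted p under 0.05. The comparisons were the genotype difference (arrays labelled Cre minus arrays labelled control) in spleen, in lymph node and averaged over both, the difference of that effect between tissues, and lymph node minus spleen within each genotype label. Nothing in the labels says whether replicates are separate animals, so p-values measure only the spread between these samples. Cd40 and Xcr1 were also given an exact two-sided permutation test, which cannot fall below 0.1 with 3 arrays against 3. Plots were drawn in matplotlib 3.10.9 (Python 3.11.15).

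Gene lists, 27 in number, were fixed before the data were examined: CD40 licensing, NF-kB pathway, cDC1 identity, Migratory maturation, MHC class II, MHC class I and cross-presentation, Pattern recognition, Interferon-stimulated, Cell cycle, Cholesterol synthesis, Chemotaxis and adhesion, Survival and apoptosis, T cell inhibitory and tolerance, Immediate early and dissociation stress, Ribosomal proteins, Oxidative phosphorylation, B cells, T cells, NK cells, cDC2, pDC, Macrophages and monocytes, Langerhans cells and keratinocytes, Neutrophils, Erythroid cells, Stromal and endothelial cells, and Sex-linked. Of their 517 genes, 454 were measured. Some genes were in several lists, and Cd40 was itself a member of CD40 licensing and of Migratory maturation. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists, and beside it with camera at an estimated correlation and with fry. The rule for named genes, also fixed before the data were examined, took Cd40 and Xcr1, the 10 called genes with the largest rise and the 10 with the largest fall among genes whose groups did not overlap, where fewer than 6 genes were called the 5 smallest unadjusted p in each direction, up to 4 members of each list described, and the 25 measured genes on either side of Xcr1. Which lists had their members described in each comparison was decided after the results were seen.

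The labels number the arrays 1 to 3 in every group. Deviations from the group means correlated across genes between arrays with the same number at r of 0.573 to 0.729 for number 1, 0.309 to 0.449 for number 2 and 0.293 to 0.466 for number 3, against a median of -0.449 for different numbers. That contrast came from number 1: arrays numbered 2 and 3 correlated with each other at 0.177 to 0.557, much as within each of these numbers. For 8 of 12 arrays, the mean correlation with arrays of other groups was highest for their own number. The numbers were taken to pair the arrays on this basis, which is clear for number 1 alone, and a fit with the number as a block was run beside the fit without it.

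The code was tested on simulated data made from the real arrays' means and spread, with 200 of the 19938 genes changed in each of 20 runs. In the spleen genotype comparison, 46.9% of genes changed by 1.5-fold, 83.4% of those changed by 2-fold and 99.0% of those changed by 4-fold were called. In the lymph node genotype comparison the shares were 45.7%, 81.9% and 98.4%. With the replicate block, in data simulated with it, they were 70.6%, 93.8% and 99.7% in spleen and 69.1%, 94.6% and 99.8% in lymph node. The simulated noise was independent between genes and arrays, and the genotype labels were taken as right. Without the block, the real deviations were instead shared between arrays, most clearly those numbered 1. The shares test the code and may not hold for the real genotype comparisons.

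Alternatives tried were the replicate block, filters at the 25th percentile and at the median of level, all probe sets, the mean of a gene's probe sets, repeated quantile normalization, centring on array medians, eBayes without trend or with robust fitting, array weights, fits with only the compared groups, a 2-fold threshold and each array left out. Leaving out every array of 1 number, and the block without replicate 3, were added after seeing the data. A fit with inferred sex was not run, because all arrays looked female.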

Results

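Gene expression was measured in cDC1 from 2 tissues and 2 genotypes, as 4 groups of 3 arrays each, with 19938 genes tested. The series was made to compare steady-state cDC1 with and without CD40, the receptor through which helper T cells license dendritic cells. Median intensities per array ran from 66.1 to 74.4. Tissue was the main axis of variation: the first principal component held 79.5% of the variance and parted spleen from lymph node, and the second, with 11.2%, set the replicate 1 arrays of all 4 groups apart.

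Cd40 (probe set 10478678, chromosome 2), the gene targeted by the cross, did not follow the genotype labels in every array. In spleen its intensity was 572, 525 and 309 on the arrays labelled control and 365, 214 and 569 on the arrays labelled Cre, for replicates 1, 2 and 3. In lymph node it was 2138, 2777 and 1542 on the arrays labelled control and 1427, 1388 and 3358 on the arrays labelled Cre. The ratio of Cre to control was thus 0.638 and 0.407 in spleen and 0.668 and 0.5 in lymph node for replicates 1 and 2, but 1.84 and 2.18 for replicate 3. The log2 difference was -0.35 in spleen (SE 0.40, n = 3 per group, exact permutation p = 0.6, limma adjusted p = 1) and -0.15 in lymph node (SE 0.40, n = 3 per group, exact permutation p = 0.8, limma adjusted p = 1). Probes outside the deleted exons would not report the deletion, and the probe positions were not used here. For this reason the genotype is given below only as the label of an array, and every direction drawn from it rests on those labels.

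Xcr1 (probe set 10597996, chromosome 9), the chemokine receptor gene that carries the Cre, differed little between the labels. Its log2 difference was -0.20 in spleen (SE 0.22, n = 3 per group, exact permutation p = 0.5) and -0.04 in lymph node (exact permutation p = 0.9, n = 3 per group). Across tissues both genes differed strongly, as the plot of Cd40 and Xcr1 by array shows.

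**Figure D1:**
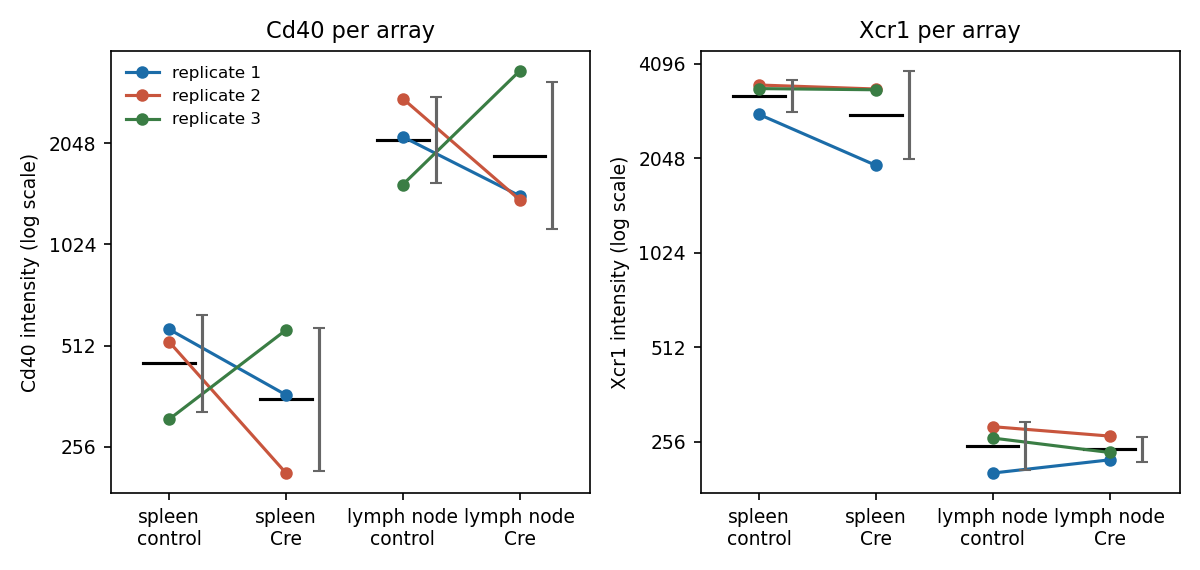
Intensity (log scale) of Cd40 and Xcr1 on each array, with lines joining arrays of the same replicate number within a tissue; black bars are group means of log2 values and grey bars 1 SD, with 3 arrays per group. Cd40 is lower on the array labelled Cre for replicates 1 and 2 and higher for replicate 3 in both tissues, while Xcr1 separates the tissues.

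In spleen cDC1, no gene was called between the arrays labelled Cre and those labelled control, but genes of the mature, CCR7-high dendritic cell state lay lower as a group on the arrays labelled Cre. The Migratory maturation list had a median log2 difference of -0.26 over 31 measured members, lower by camera (adjusted p = 5.09e-09; adjusted p = 0.613 with an estimated correlation). Without spleen Cre replicate 2 the median was -0.14. None of its members passed alone. Il12b, the shared subunit of IL-12 and IL-23, was at -0.61 (SE 0.27, n = 3 per group) and Ccl22, a chemokine that draws CCR4-bearing T cells, at -0.58 (SE 0.27). Il12b was lower on the array labelled Cre for all 3 replicate numbers, with ratios of 0.596, 0.606 and 0.772. Its unadjusted limma p was 0.0412 without the block and 2.27e-05 with it (limma adjusted p = 0.453 with the block). Pdcd1lg2, the PD-1 ligand PD-L2, was at -0.51 (SE 0.25) and Marcksl1 at -0.33 (SE 0.14). The T cell inhibitory and tolerance list was lower by camera too, with a median of -0.14 over 22 members (adjusted p = 0.000876; adjusted p = 0.0622 with an estimated correlation). Its members Lag3, an inhibitory receptor for MHC class II, and Aldh1a2, which makes retinoic acid, were at -0.39 (SE 0.11) and -0.47 (SE 0.15), and Socs3, a brake on cytokine signalling, at -0.26 (SE 0.13). The T cell inhibitory call was lost without spleen control replicate 3 (adjusted p = 0.0768) or spleen Cre replicate 1 (0.0544).

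The CD40 licensing list, genes known to be induced by CD40 ligation, was lower in spleen by camera, with a median of -0.17 over 27 members (adjusted p = 0.0334; adjusted p = 0.613 with an estimated correlation). Cd40, the targeted gene, was among the members of this list and of Migratory maturation. The lists also share Il12b, Ccl22, Ccl17, Cd80, Cd83, Cd274, Il15, Il15ra and Traf1, so their calls are not separate evidence. Besides Il12b and Ccl22, Tnfsf9, the ligand of 4-1BB, was at -0.58 (SE 0.32, n = 3 per group) and Cd80, a costimulatory ligand of CD28, at -0.24 (SE 0.14). The NF-kB pathway list had a median of -0.07 and did not pass (adjusted p = 0.112; adjusted p = 0.940 with an estimated correlation). It passed with the replicate block (0.0455), among genes above the median level (0.00312) and without spleen control replicate 1 (0.00160), spleen Cre replicate 3 (0.0184) or all replicate 1 arrays (0.00134), and its adjusted p ran from 0.00134 to 0.992 over the alternatives. Its members were Map3k14, the kinase NIK, at -0.40 (SE 0.24), Relb at -0.34 (SE 0.24), Traf1 at -0.29 (SE 0.21) and Nfkbia, the NF-kB inhibitor, at -0.24 (SE 0.14). Macrophages and monocytes was lower, with a median of -0.09 over 17 members (adjusted p = 0.0439; adjusted p = 0.8 with an estimated correlation). Cell cycle was higher, with a median of 0.04 over 29 members (adjusted p = 0.0439; adjusted p = 0.940 with an estimated correlation). B cells was higher by the test and the mean of 0.08 over 13 members but not by its median of -0.01 (adjusted p = 0.0439; adjusted p = 0.867 with an estimated correlation). With the block, Cell cycle (0.0862) and B cells (0.111) no longer passed, nor did they among genes above the median level (0.476 and 0.921, B cells with its direction turned). The CD40 licensing call was lost without spleen control replicates 1 or 3 (0.193, 0.216) or spleen Cre replicates 1 or 2 (0.0596, 0.152). The Macrophages and monocytes call was lost without spleen control replicates 1 or 3 (0.193, 0.216) or spleen Cre replicate 2 (0.442). The B cells call was lost without spleen control replicates 1 or 3 (0.193, 0.0768) or spleen Cre replicates 1, 2 or 3 (0.0637, 0.121, 0.152). The Cell cycle call was lost without spleen control replicates 1 or 3 (0.961, 0.0799) or spleen Cre replicates 2 or 3 (0.600, 0.955), with its direction turned in 3 of these. Without all replicate 1 arrays the calls of B cells (0.205) and Macrophages and monocytes (0.0808) were lost, and without all replicate 2 arrays those of B cells (0.0808) and Cell cycle (0.362). Without all replicate 3 arrays the calls of CD40 licensing (0.133), Macrophages and monocytes (0.133), B cells (0.164) and Cell cycle (0.894) were lost.

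By single genes, limma called 0 of 19938 genes in spleen with or without the replicate block. At an unadjusted p under 0.05 there were 357 genes (886 with the block), against 997 that chance gives. Without the block all the genotype comparisons had fewer such genes than chance gives. The SEs of that fit include deviations shared by same-numbered arrays, so its single-gene p-values ran large there. None of the genes with the smallest unadjusted p passed. On the higher side these were F630028O10Rik at 0.61 (SE 0.13), Ifi203, an interferon-inducible gene, at 0.73 (SE 0.19), Cd226, a costimulatory receptor, at 0.57 (SE 0.15), Abcd2 at 0.51 (SE 0.14) and Agmo at 0.46 (SE 0.13). On the lower side they were 4933405O20Rik at -0.37 (SE 0.10), Ticam2, an adaptor of Toll-like receptor 4, at -0.41 (SE 0.11), Lag3 at -0.39 (SE 0.11), Rcan1, an inhibitor of calcineurin, at -0.52 (SE 0.15) and Sult2b1 at -0.43 (SE 0.12). Of the 29 measured neighbours of Xcr1, 25 before it and 4 after, 0 were called by limma and 1 had an unadjusted p under 0.05. With array weights limma called 51 genes, 26 higher and 25 lower. No list member passed when adjusted over the list alone, with a count of 0 for each of the 6 called lists by limma; fry called 0 lists.

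In migratory lymph node cDC1, the interferon response was lower as a group on the arrays labelled Cre. The Interferon-stimulated list had a median log2 difference of -0.14 over 26 measured members (camera adjusted p = 0.00155; adjusted p = 0.988 with an estimated correlation). Irf7, the regulator that amplifies type I interferon, was at -0.69 (SE 0.17, n = 3 per group) and lower on the array labelled Cre for all 3 replicate numbers. Ifit1, which binds viral RNA, was at -0.58 (SE 0.16), also lower for all 3. Ddx60 at -0.25 (SE 0.08) and Rtp4 at -0.41 (SE 0.17) were the next members. None passed over all genes, and 2 were lower when adjusted over the list alone. The list's call was lost without lymph node control replicate 3 (adjusted p = 0.394) or lymph node Cre replicate 2 (0.0675), without all arrays of replicate 2 (0.101) or replicate 3 (0.304), and among genes above the median level (0.345).

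Genes of CD40 and NF-kB signalling did not pass as lists in lymph node with all arrays and no block. The CD40 licensing list had a median of -0.07 (camera adjusted p = 0.323) and passed without lymph node Cre replicate 3 (0.0400) and without all replicate 3 arrays (0.00899). Members were Il12a and Il23a, cytokine subunits, at -0.30 (SE 0.13) and -0.27 (SE 0.12), Il27 at -0.31 (SE 0.18) and Icam1, an adhesion ligand, at -0.37 (SE 0.27). The NF-kB pathway list, with a median of -0.13, did not pass (adjusted p = 0.269; adjusted p = 0.988 with an estimated correlation) but passed with the replicate block (0.0306). It also passed without lymph node control replicate 1 (1.96e-05), lymph node Cre replicates 2 or 3 (0.000966, 0.0458) or all replicate 2 arrays (0.0259), and turned to higher without lymph node control replicate 3 (0.712) or lymph node Cre replicate 1 (0.256). The same list was lower on the replicate 1 arrays of all 4 groups, by medians of -0.15 to -0.58, against the genotype median of -0.13. MHC class I and cross-presentation, with a median of -0.08, did not pass (adjusted p = 0.323; adjusted p = 0.988 with an estimated correlation) but passed with the block (0.0135). It also passed without lymph node control replicate 1 (0.0396) and turned to higher without lymph node Cre replicate 1 (0.883). The NF-kB members Nfkb2, Traf2, Ikbkg and Tnfaip3 were at -0.36 (SE 0.24), -0.34 (SE 0.21), -0.20 (SE 0.14) and -0.22 (SE 0.26). Limma called 0 genes in lymph node with or without the block, with 402 at an unadjusted p under 0.05 (1360 with the block) against 997 by chance. The genes with the smallest unadjusted p did not pass. On the higher side they were the histone gene H2ac8 at 0.47 (SE 0.11) and 2410018L13Rik at 0.32 (SE 0.09), the latter at background on the arrays labelled control. The others, Ifna13, Olfr618 and Tas2r134, were at background in all 4 groups, so their differences are of background signal and are not given. On the lower side they were Nicn1 at -0.53 (SE 0.12), Arsi at -0.42 (SE 0.10), Mfsd9 at -0.40 (SE 0.10), Irf7 at -0.69 (SE 0.17) and Sdr42e1 at -0.33 (SE 0.08). With array weights limma called 2 genes, Ifi206 and Olfr618, the latter at background, and with the block and no replicate 3 arrays it called 1, Csf1, all named after their values were seen. Of the 29 neighbours of Xcr1, limma called 0, with 0 at an unadjusted p under 0.05 (2 with the block); fry called 0 lists.

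Averaged over both tissues, maturation and CD40-related genes lay lower on the arrays labelled Cre. Camera put Migratory maturation lower (median -0.13, adjusted p = 1.13e-05; adjusted p = 0.550 with an estimated correlation). In lymph node alone this list did not pass (camera adjusted p = 0.811). Its medians by same-numbered pair were -0.03, -0.05 and -0.04 in lymph node and -0.29, -0.42 and -0.07 in spleen. The averaged call therefore came mainly from spleen and does not show an effect shared by both tissues. CD40 licensing was lower (median -0.13, adjusted p = 0.00820; adjusted p = 0.506 with an estimated correlation), as was NF-kB pathway (median -0.12, adjusted p = 0.0110; adjusted p = 0.905 with an estimated correlation). Interferon-stimulated was lower (median -0.05, adjusted p = 0.0212; adjusted p = 0.550 with an estimated correlation). So were T cell inhibitory and tolerance (median -0.07, adjusted p = 0.0358, or 0.506 with an estimated correlation) and Macrophages and monocytes (median -0.09, adjusted p = 0.0188, or 0.550 with an estimated correlation). Interferon-stimulated did not pass in spleen alone (camera adjusted p = 0.864), nor T cell inhibitory and tolerance in lymph node alone (0.932). Both differed between tissues by camera, as given below, so their averaged calls do not show a shared effect either. Cell cycle was higher (median 0.04, adjusted p = 0.0326; adjusted p = 0.905 with an estimated correlation), and so was B cells (median 0.05, adjusted p = 0.0110; adjusted p = 0.630 with an estimated correlation). MHC class I and cross-presentation did not pass (adjusted p = 0.478; adjusted p = 0.905 with an estimated correlation) but passed with the block (0.0417), and turned to higher without lymph node Cre replicate 1 (0.832). With the block, Cell cycle (0.0675) and T cell inhibitory and tolerance (0.0675) no longer passed, and among genes above the median level Interferon-stimulated (0.246) and B cells (0.589) did not. Limma called 0 genes, with 383 at an unadjusted p under 0.05 (1065 with the block), and fry called 0 lists; Cd40 was at -0.25 (SE 0.28) and Xcr1 at -0.12 (SE 0.15). None of the genes with the smallest unadjusted p passed. On the higher side they were H2ac8 at 0.30 (SE 0.08), at background on the spleen arrays labelled control, Agmo at 0.36 (SE 0.09) and Cltrn at 0.37 (SE 0.10), at background on the lymph node arrays labelled control, with Olfr307, at background in 3 groups, and Olfr618, at background in all 4. On the lower side they were Zfp663 at -0.21 (SE 0.05), G530011O06Rik at -0.23 (SE 0.06), Ikzf3 at -0.24 (SE 0.07), Gsc2 at -0.26 (SE 0.07) and Zfp239 at -0.26 (SE 0.07). Zfp663 was at background on the arrays labelled Cre. Of the 29 neighbours of Xcr1, limma called 0, with 1 at an unadjusted p under 0.05 (4 with the block).

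Each of the averaged list calls was lost when some single array was left out. Migratory maturation was lost only without lymph node Cre replicate 1 (adjusted p = 0.0517), and its adjusted p ran from 1.95e-09 to 0.784 over the alternatives. CD40 licensing was lost without spleen control replicates 1 or 3 (0.0708, 0.0557) or lymph node Cre replicate 1 (0.102). NF-kB pathway was lost without spleen control replicate 3 (0.138), spleen Cre replicate 1 (0.0936), lymph node control replicates 2 or 3 (0.0782, 0.578) or lymph node Cre replicate 1 (0.888). Interferon-stimulated was lost without spleen control replicates 1 or 3 (0.0848, 0.132), spleen Cre replicate 1 (0.0941), lymph node control replicate 3 (0.578) or lymph node Cre replicates 1 or 2 (0.102, 0.0948). Cell cycle was lost without spleen control replicates 1 or 3 (0.813, 0.0557), spleen Cre replicates 2 or 3 (0.966, 0.741), lymph node control replicate 1 (0.293) or lymph node Cre replicates 1 or 2 (0.202, 0.0645). T cell inhibitory and tolerance was lost without spleen control replicates 1 or 3 (0.0816, 0.166), spleen Cre replicates 1 or 2 (0.178, 0.131), lymph node control replicates 2 or 3 (0.0864, 0.2) or lymph node Cre replicates 1 or 2 (0.230, 0.0656). B cells was lost without spleen control replicate 1 (0.0708), lymph node control replicate 3 (0.239) or lymph node Cre replicate 1 (0.145). Macrophages and monocytes was lost without spleen control replicates 1 or 3 (0.0968, 0.0902), spleen Cre replicate 2 (0.207), lymph node control replicate 1 (0.117) or lymph node Cre replicates 1 or 2 (0.0517, 0.0707). Without all replicate 1 arrays, T cell inhibitory and tolerance (0.197) and Macrophages and monocytes (0.156) were lost. Without all replicate 2 arrays, Cell cycle, T cell inhibitory and tolerance, B cells and Macrophages and monocytes were lost (each 0.0725). Without all replicate 3 arrays, NF-kB pathway (0.484), Interferon-stimulated (0.680), Cell cycle (0.364), T cell inhibitory and tolerance (0.159) and B cells (0.148) were lost.

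The genotype effect differed between tissues for 3 lists by camera. Migratory maturation had a lymph node effect above its spleen effect (median difference 0.20, camera adjusted p = 0.00333; adjusted p = 0.988 with an estimated correlation). Members were Pdcd1lg2 at 0.53 (SE 0.36), Cd80 at 0.28 (SE 0.20), Socs2, a cytokine signalling inhibitor, at 0.29 (SE 0.22) and Tmem123 at 0.20 (SE 0.16). T cell inhibitory and tolerance also lay above (median 0.20, adjusted p = 0.0236; adjusted p = 0.289 with an estimated correlation). Members were the cytokine Il10 at 0.42 (SE 0.19), Lag3 at 0.31 (SE 0.16), Ido2 at 0.26 (SE 0.17) and Aldh1a1 at 0.19 (SE 0.12). Interferon-stimulated lay below (median -0.17, adjusted p = 0.0189; adjusted p = 0.988 with an estimated correlation). Members were Irf7 at -0.81 (SE 0.24), Ifit1 at -0.54 (SE 0.22), Isg20 at -0.43 (SE 0.28) and Rtp4 at -0.31 (SE 0.25). None of these members passed alone. Among genes above the median level Interferon-stimulated no longer passed (0.430), and CD40 licensing, which did not pass otherwise (adjusted p = 0.924; adjusted p = 0.988 with an estimated correlation), passed (0.0135), with its lymph node effect above its spleen effect. Migratory maturation was lost without spleen Cre replicate 2 (0.224), lymph node control replicate 1 (0.485) or lymph node Cre replicates 2 or 3 (0.151, 0.245). Interferon-stimulated was lost without spleen control replicate 2 (0.0692), spleen Cre replicate 2 (0.112), lymph node control replicate 3 (0.482) or lymph node Cre replicate 2 (0.151). T cell inhibitory and tolerance was lost without spleen control replicate 3 (0.185), spleen Cre replicates 1 or 2 (0.146, 0.112), lymph node control replicate 1 (0.328) or lymph node Cre replicates 2 or 3 (0.151, 0.159). Without all replicate 2 arrays all 3 calls were lost (0.144 for Migratory maturation, 0.383 for Interferon-stimulated and 0.104 for T cell inhibitory and tolerance). Without all replicate 3 arrays Interferon-stimulated (0.212) and T cell inhibitory and tolerance (0.0797) were lost, and the latter also without all replicate 1 arrays (0.176). Limma called 0 genes, with 326 at an unadjusted p under 0.05 (1145 with the block), and fry called 0 lists. Cd40 was at 0.20 (SE 0.56) and Xcr1 at 0.16 (SE 0.30). The genes with the smallest unadjusted p did not pass. On the higher side they were Ifna13, at background in all 4 groups, Galnt15 at 0.48 (SE 0.13), 2410018L13Rik at 0.46 (SE 0.12), at background on the lymph node arrays labelled control, A430093F15Rik at 0.63 (SE 0.18) and Sbpl at 0.55 (SE 0.16). On the lower side they were Pgm2l1 at -0.71 (SE 0.15), Sdr42e1 at -0.51 (SE 0.12), Slc25a14 at -0.67 (SE 0.16), Arv1 at -0.63 (SE 0.17) and Rpgr at -0.65 (SE 0.19). With array weights limma called 3 genes, Ifi206, Jmy and Pgm2l1, named after their values were seen.

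Migratory lymph node cDC1 differed from splenic cDC1 in 5207 of 19938 genes. Tissue, CD11c gate and migratory state changed together in both tissue comparisons, so their parts cannot be told apart. Rises and falls below mean levels higher or lower in lymph node than in spleen. Among arrays labelled control, Cd40 rose by 2.21 on the log2 scale (SE 0.40, n = 3 per group, limma adjusted p = 0.000684) and Xcr1 fell by 3.71 (SE 0.22, limma adjusted p = 2.51e-08). The largest rises were of Clu, a secreted chaperone, at 5.24 (SE 0.23), Elobl at 5.09 (SE 0.28), the semaphorin Sema6d at 5.04 (SE 0.29) and Cdh2, N-cadherin, at 4.97 (SE 0.15). S100a4, a calcium-binding protein, rose by 4.92 (SE 0.35), H2-M2, a nonclassical MHC class I gene, by 4.88 (SE 0.29), and F11r, a junctional adhesion molecule, by 4.78 (SE 0.37). Pygl, glycogen phosphorylase, rose by 4.70 (SE 0.18), Mtss2 by 4.62 (SE 0.17) and Mfge8, which bridges phagocytes to dying cells, by 4.6 (SE 0.19). The largest falls were of Plac8 at -5.52 (SE 0.27), Scimp, an adaptor in MHC class II signalling, at -5.43 (SE 0.24) and Havcr2, the inhibitory receptor TIM-3, at -4.93 (SE 0.24). Next were Slc9a9, an endosomal exchanger, at -4.92 (SE 0.23), Dcstamp at -4.87 (SE 0.26) and P2ry14, a receptor for UDP-sugars, at -4.77 (SE 0.18). Then came Treml4 at -4.67 (SE 0.27), Cyth4 at -4.67 (SE 0.24), the lysosomal amidase Naaa at -4.6 (SE 0.27) and Tlr3, the sensor of double-stranded RNA, at -4.57 (SE 0.22). Limma called 5207 genes, 2581 higher and 2626 lower, of which 2316 differed at least 2-fold (1095 higher, 1221 lower). When arrays were left out, the count ran from 2865 (without all replicate 3 arrays) to 6906 (without all replicate 1 arrays).

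Genes of the mature state and of the NF-kB system were both higher in the lymph node cells. In Migratory maturation, 28 of 31 measured members rose and 1 fell, with Slco5a1 at 4.43 (SE 0.21), Socs2 at 4.08 (SE 0.16), Il15ra, which presents IL-15 to T and NK cells, at 4.05 (SE 0.18) and Nudt17 at 3.99 (SE 0.20; camera adjusted p = 3.51e-20; adjusted p = 0.0661 with an estimated correlation). In NF-kB pathway, 16 of 20 rose and 0 fell by limma (adjusted p = 4.83e-10; adjusted p = 0.161 with an estimated correlation). Examples were Birc2, an inhibitor of apoptosis that also restrains NIK, at 3.12 (SE 0.23), Relb at 2.35 (SE 0.24), Tnip1 at 1.98 (SE 0.16) and Nfkbia at 1.49 (SE 0.14). In CD40 licensing, 15 of 27 rose and 7 fell (adjusted p = 0.00446; adjusted p = 0.161 with an estimated correlation). Examples were Slamf1 at 4.16 (SE 0.12), Il15 at 3.51 (SE 0.22) and Ccl22 at 2.99 (SE 0.27). Adjusted over the list alone, the counts were 29 higher and 1 lower for Migratory maturation, 17 higher for NF-kB pathway, and 16 higher and 7 lower for CD40 licensing.

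Most genes of the cDC1 identity list fell, and so did cell cycle genes. In cDC1 identity, 20 of 26 members fell and 3 rose, with Tlr3, Hepacam2 at -4.33 (SE 0.19), the endosomal Rab7b at -4.29 (SE 0.21) and the scavenger receptor Cd36 at -4.26 (SE 0.17; camera adjusted p = 2.28e-14; adjusted p = 0.0661 with an estimated correlation). In Cell cycle, 27 of 29 fell and 0 rose by limma (adjusted p = 1.90e-18; adjusted p = 0.109 with an estimated correlation). Examples were the cyclins Ccnb2 at -2.90 (SE 0.23) and Ccna2 at -2.27 (SE 0.19), Birc5, survivin, at -2.30 (SE 0.20) and Pcna, the replication clamp, at -1.81 (SE 0.13). In Pattern recognition, 10 of 23 fell and 3 rose (adjusted p = 0.00446; adjusted p = 0.0661 with an estimated correlation). Examples were Clec9a, a receptor for dead cells, at -4.11 (SE 0.23), the inflammasome sensor Nlrp3 at -4.07 (SE 0.12) and Cd14 at -3.86 (SE 0.43). Adjusted over the list alone, 20 fell and 4 rose in cDC1 identity, 28 fell in Cell cycle, and 10 fell and 4 rose in Pattern recognition.

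Antigen presentation genes divided. In MHC class II, 8 of 12 fell and 3 rose (camera adjusted p = 0.000952; adjusted p = 0.0661 with an estimated correlation). Examples were H2-Ob and H2-Oa, the chains of a peptide-loading modulator, at -3.64 (SE 0.16) and -2.41 (SE 0.23), the class II transactivator Ciita at -3.63 (SE 0.36) and H2-DMa at -2.45 (SE 0.17). MHC class I and cross-presentation did not pass as a list (adjusted p = 0.612), with 7 of 19 higher and 4 lower: Wdfy4, needed for cross-presentation by cDC1, was at -3.78 (SE 0.22), Rab43 at -1.54 (SE 0.26), the proteasome activator Psme2 at 1.02 (SE 0.14) and B2m at 0.60 (SE 0.09), and its mean of -0.02 and median of 0.24 differed in sign. T cell inhibitory and tolerance did not pass either (adjusted p = 0.954), with 7 of 22 higher, among them Socs2 and Cd200 at 1.53 (SE 0.17), and 7 lower, among them Havcr2 and Tgfb1 at -2.63 (SE 0.16); its median was 0.09 and its mean -0.05. Adjusted over the list alone, the counts were 9 lower and 3 higher for MHC class II, 8 higher and 4 lower for class I, and 7 higher and 7 lower for T cell inhibitory and tolerance.

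Sterol synthesis rose and trafficking genes were exchanged. In Cholesterol synthesis, 13 of 19 rose and 1 fell (camera adjusted p = 8.90e-06; adjusted p = 0.109 with an estimated correlation). Examples were Idi1 at 3.48 (SE 0.15), Fdft1, squalene synthase, at 2.43 (SE 0.15), Sc5d at 1.5 (SE 0.21) and Hmgcs1 at 1.45 (SE 0.17). In Chemotaxis and adhesion, 14 of 27 fell and 7 rose (adjusted p = 0.00356; adjusted p = 0.1 with an estimated correlation). Examples were the integrin chains Itgb2 at -3.54 (SE 0.19) and Itgb8 at 4.08 (SE 0.23) and the chemokine receptors Cxcr3 at -3.00 (SE 0.15) and Ccr9 at -2.67 (SE 0.14). Interferon-stimulated had 13 of 26 higher and 4 lower (adjusted p = 0.0422; adjusted p = 0.389 with an estimated correlation; 0.0543 with the block). Examples were Ifit1 at 2.31 (SE 0.16), Usp18 at 2.14 (SE 0.17), Irf7 at -1.73 (SE 0.17) and the chemokine Cxcl9 at -2.90 (SE 0.29). That call was lost without spleen control replicates 1 or 2 (0.0757, 0.0606) or lymph node control replicates 2 or 3 (0.0640, 0.188), without all arrays of replicate 2 (0.0864) or replicate 3 (0.0894), and among genes above the median level (0.344). Survival and apoptosis did not pass as a list (adjusted p = 0.0578), although 8 of 18 members rose and 3 fell. Examples were the death receptor Fas at 2.40 (SE 0.19), its inhibitor Cflar at 2.30 (SE 0.20) and Birc3 at 1.44 (SE 0.17). Immediate early and dissociation stress had 10 of 22 lower and 1 higher (adjusted p = 0.00446; adjusted p = 0.489 with an estimated correlation). Examples were Egr2 at -3.58 (SE 0.43), Nr4a1 at -3.04 (SE 0.37), Egr3 at -2.06 (SE 0.34) and Btg2 at -1.60 (SE 0.24). The Immediate early call was lost without lymph node control replicate 1 (0.0679) and among genes above the median level (0.0756). Adjusted over the list alone, the counts were 13 higher and 1 lower for Cholesterol synthesis, 15 lower and 7 higher for Chemotaxis and adhesion, 13 higher and 5 lower for Interferon-stimulated, 9 higher and 4 lower for Survival and apoptosis, and 11 lower and 1 higher for Immediate early and dissociation stress.

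**Figure D2:**
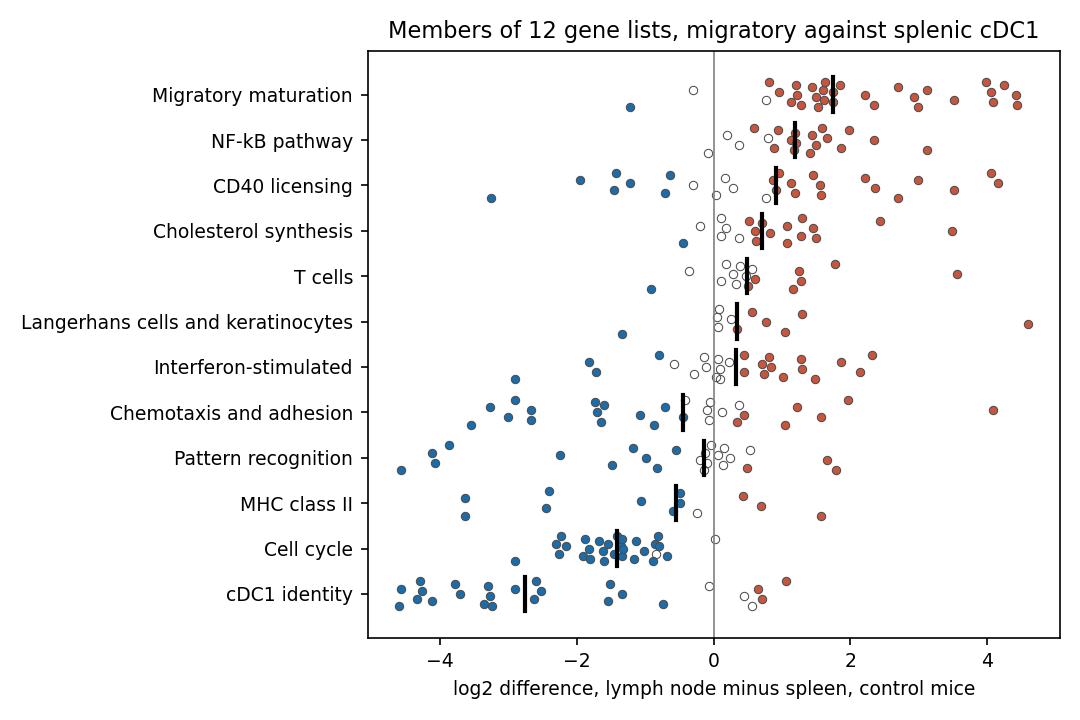
Log2 difference between lymph node and spleen cDC1 on arrays labelled control for each measured member of 12 gene lists; filled points were called by limma (red higher, blue lower), open points were not, and black bars are list medians. Migratory maturation (median 1.75) and cDC1 identity (median -2.76) lie at opposite ends.

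Markers of other cells were also compared between the tissues. The Langerhans cells and keratinocytes list had 6 of 11 higher and 1 lower (camera adjusted p = 0.00446; adjusted p = 0.161 with an estimated correlation). Examples were Mfge8, Perp at 1.30 (SE 0.19), the adhesion molecule Epcam at 1.04 (SE 0.17) and Lamb3 at 0.77 (SE 0.11). T cells had 7 of 16 higher and 1 lower (adjusted p = 0.00256; adjusted p = 0.277 with an estimated correlation). Examples were the IL-7 receptor gene Il7r at 3.56 (SE 0.27), Lat at 1.25 (SE 0.19), Cd8b1 at 1.16 (SE 0.17) and Cd5 at -0.91 (SE 0.19). NK cells had 3 of 12 lower, Klrk1 at -1.66 (SE 0.18), Tbx21 at -0.45 (SE 0.15) and Klre1 at -0.43 (SE 0.15; adjusted p = 0.0387; adjusted p = 0.489 with an estimated correlation). Macrophages and monocytes had 3 of 17 lower, Lyz2 at -3.59 (SE 0.26), Hmox1 at -2.90 (SE 0.25) and Ccr2 at -1.64 (SE 0.21), and 1 higher, Vcam1 at 1.04 (SE 0.16; adjusted p = 0.0324; adjusted p = 0.354 with an estimated correlation; 0.0529 with the block). cDC2 had 3 of 15 lower, Clec12a at -2.15 (SE 0.21), Cd300a at -1.61 (SE 0.15) and Itgam at -0.45 (SE 0.11), and 1 higher, the transcription factor Irf4 at 1.21 (SE 0.25; adjusted p = 0.0422; adjusted p = 0.239 with an estimated correlation; 0.0565 with the block). These last 3 calls were lost without spleen control replicate 1 (0.128, 0.0745 and 0.0745), NK cells also without spleen control replicate 3 (0.0618) or lymph node control replicates 2 or 3 (0.0640, 0.05), and cDC2 without spleen control replicate 3 (0.0548) or lymph node control replicate 1 (0.112). Without all replicate 1 arrays NK cells (0.101), Macrophages and monocytes (0.0914) and cDC2 (0.149) were lost, and without all replicate 3 arrays NK cells (0.0679). Among genes above the median level, Langerhans cells and keratinocytes (0.426), NK cells (0.379), Macrophages and monocytes (0.159) and cDC2 (0.379) did not pass.

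Other lists were compared between the tissues as well. B cells did not pass (adjusted p = 0.145) although Fcrla at -3.45 (SE 0.34), Ms4a1, CD20, at -2.20 (SE 0.18) and Bank1 at -1.63 (SE 0.16) fell, and its median of 0.05 and mean of -0.53 differed in sign. pDC did not pass (adjusted p = 0.849), with Spib at 1.54 (SE 0.20), Tcf4 at 0.85 (SE 0.15) and Pacsin1 at -0.90 (SE 0.18). Oxidative phosphorylation was lower, with 6 of 26 lower and 1 higher (adjusted p = 0.0163; adjusted p = 0.506 with an estimated correlation), with Uqcrc1 at -0.79 (SE 0.14), Atp5a1 at -0.76 (SE 0.16), Ndufa9 at -0.70 (SE 0.14) and Atp5b at -0.56 (SE 0.13), and was lost without spleen control replicate 1 (0.0833) or lymph node control replicate 2 (0.0674). Ribosomal proteins was lower, with 2 of 20 lower (adjusted p = 0.0387; adjusted p = 0.734 with an estimated correlation), and was lost without spleen control replicate 1 (0.128) or lymph node control replicates 2 or 3 (0.0892, 0.110), or without all arrays of replicate 2 (0.0540) or replicate 3 (0.133). Among genes above the median level, neither Oxidative phosphorylation (0.132) nor Ribosomal proteins (0.187) passed. Neutrophils (adjusted p = 0.532), Erythroid cells (0.639), Stromal and endothelial cells (0.954) and Sex-linked (0.954) did not pass.

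Among arrays labelled Cre, the tissue difference ran along the same genes. Cd40 rose by 2.41 on the log2 scale (SE 0.40, n = 3 per group, limma adjusted p = 0.000324) and Xcr1 fell by 3.55 (SE 0.22, limma adjusted p = 3.81e-08). Clu at 5.48 (SE 0.23), Sema6d at 5.18 (SE 0.29), H2-M2 at 5.11 (SE 0.29), S100a4 at 4.99 (SE 0.35), Cdh2 at 4.95 (SE 0.15), Mtss2 at 4.82 (SE 0.17), F11r at 4.81 (SE 0.37), Insl6 at 4.74 (SE 0.34), Pygl at 4.65 (SE 0.18) and Tmem150c at 4.64 (SE 0.24) rose most. Plac8 at -5.64 (SE 0.27), Scimp at -5.12 (SE 0.24), Slc9a9 at -4.95 (SE 0.23), Havcr2 at -4.91 (SE 0.24), Kmo, an enzyme of tryptophan breakdown, at -4.85 (SE 0.37), Treml4 at -4.77 (SE 0.27), Tlr3 at -4.69 (SE 0.22), Serpinb8 at -4.63 (SE 0.13), Naaa at -4.49 (SE 0.27) and Rab7b at -4.43 (SE 0.21) fell most. Limma called 5648 genes, 2618 higher and 3030 lower, of which 2369 differed at least 2-fold (950 higher, 1419 lower). When arrays were left out, the count ran from 3081 (without all replicate 2 arrays) to 7684 (without all replicate 1 arrays).

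Camera called 14 lists among arrays labelled Cre. Migratory maturation had 28 of 31 higher and 1 lower (adjusted p = 3.72e-20; adjusted p = 0.0663 with an estimated correlation). Examples were Slco5a1 at 4.51 (SE 0.21), Socs2 at 4.37 (SE 0.16), Il15ra at 4.24 (SE 0.18) and Nudt17 at 4.17 (SE 0.20). CD40 licensing had 15 of 27 higher and 7 lower (adjusted p = 0.0104; adjusted p = 0.205 with an estimated correlation). Examples were Slamf1 at 4.0 (SE 0.12), Ccl22 at 3.48 (SE 0.27) and Il15 at 3.29 (SE 0.22). cDC1 identity had 20 of 26 lower and 4 higher (adjusted p = 3.14e-14; adjusted p = 0.0663 with an estimated correlation). Examples were Cd36 at -4.39 (SE 0.17) and Hepacam2 at -4.11 (SE 0.19). Cholesterol synthesis had 10 of 19 higher and 1 lower (adjusted p = 0.000509; adjusted p = 0.205 with an estimated correlation). Examples were Idi1 at 3.38 (SE 0.15), Fdft1 at 2.38 (SE 0.15), Mvd at 1.52 (SE 0.19) and Tm7sf2 at 1.21 (SE 0.17). T cells had 10 of 16 higher and 2 lower (adjusted p = 0.00325; adjusted p = 0.353 with an estimated correlation). Examples were Il7r at 3.78 (SE 0.27), Lat at 0.97 (SE 0.19), Cd8b1 at 0.86 (SE 0.17) and Cd3e at 0.77 (SE 0.13). Langerhans cells and keratinocytes had 7 of 11 higher and 1 lower (adjusted p = 0.00104; adjusted p = 0.117 with an estimated correlation). Examples were Mfge8 at 4.38 (SE 0.19), Perp at 1.77 (SE 0.19), Epcam at 1.27 (SE 0.17) and Krt14 at 0.76 (SE 0.12). The remaining calls had medians of 1.23 for NF-kB pathway (adjusted p = 8.15e-09; adjusted p = 0.205 with an estimated correlation), -1.49 for Cell cycle (adjusted p = 1.67e-18; adjusted p = 0.115 with an estimated correlation) and -0.59 for MHC class II (adjusted p = 0.000702; adjusted p = 0.0663 with an estimated correlation). Pattern recognition was at -0.27 (adjusted p = 0.00316; adjusted p = 0.0663 with an estimated correlation), Chemotaxis and adhesion at -0.62 (adjusted p = 0.00325; adjusted p = 0.112 with an estimated correlation) and Immediate early and dissociation stress at -0.52 (adjusted p = 0.00294; adjusted p = 0.444 with an estimated correlation). Oxidative phosphorylation was at -0.36 (adjusted p = 0.00316; adjusted p = 0.444 with an estimated correlation) and Ribosomal proteins at -0.20 (adjusted p = 0.0132; adjusted p = 0.640 with an estimated correlation). The Ribosomal proteins call was lost without spleen Cre replicate 1 (0.0633), lymph node Cre replicate 2 (0.0989) or all replicate 2 arrays (0.0992). Among genes above the median level, MHC class II (0.0517), Pattern recognition (0.0504), Immediate early and dissociation stress (0.124), Oxidative phosphorylation (0.128), Ribosomal proteins (0.215) and Langerhans cells and keratinocytes (0.475) did not pass. T cell inhibitory and tolerance did not pass (adjusted p = 0.448), with Cd200 at 1.80 (SE 0.17) and Tgfb1 at -2.45 (SE 0.16).

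Across all genes the tissue differences of the arrays labelled control and Cre correlated at r = 0.971, a correlation across genes, which are not independent replicates. Limma called 4528 genes in both, all in the same direction, 2080 higher and 2448 lower, where independent lists of these sizes would share 339 and 399. Another 679 genes were called among arrays labelled control alone and 1120 among arrays labelled Cre alone, but the test of the difference itself called 0 genes, with 326 at an unadjusted p under 0.05. The 2 tissue comparisons share no arrays, but they share 1 estimate of each gene's spread and measure the same difference of tissue and gate. An overlap above that of independent lists was therefore set by the design and is not separate evidence.

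**Figure D3:**
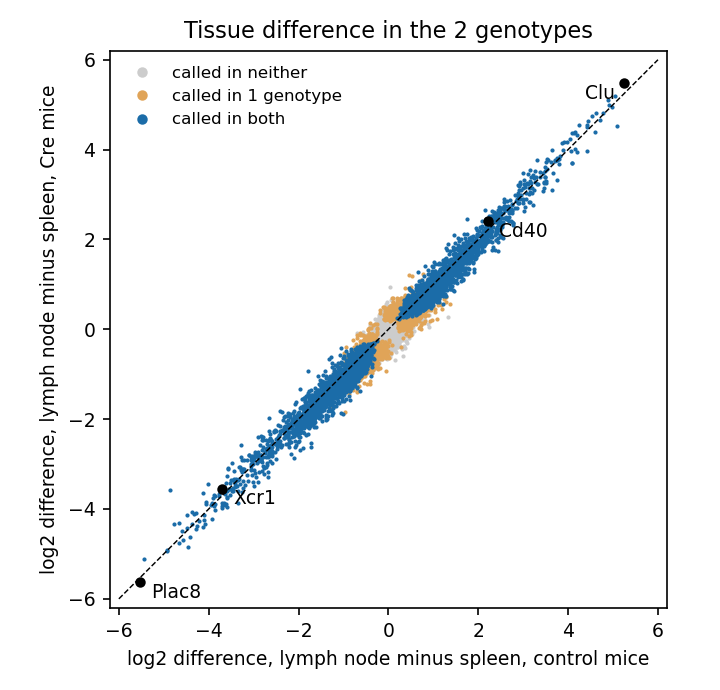
Log2 difference between lymph node and spleen cDC1 for each of 19938 genes, on arrays labelled control (horizontal axis) and on arrays labelled Cre (vertical axis), colored by whether limma called the gene in neither, in 1 or in both; the dashed line marks equal values. The genes lie along that line, from Plac8 to Clu.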

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

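Chosen or reworded only after results were seen were the tests of exchanged replicate 3 labels, incomplete deletion, a single spleen array, compressed signal range and different handling of replicate 1; a test of pair exchanges came first and the correlation of pair differences was chosen after its result, just as handling was tested after signal range had been.

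The genotype effect differed between spleen and lymph node for Migratory maturation (camera adjusted p = 0.00333), Interferon-stimulated (adjusted p = 0.0189) and T cell inhibitory and tolerance (adjusted p = 0.0236), which drew attention as differences between tissues. None of the 3 passed with an estimated correlation (adjusted p = 0.988, 0.988 and 0.289).

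Cd40 on the replicate 3 arrays of both tissues ran against the genotype labels. Incomplete deletion in a replicate 3 Cre mouse alone is argued against. Cd40 on the control replicate 3 arrays was itself low, at percentile 0.2 among genes of like level in both tissues. A different maturation of the replicate 3 mice is argued against only as the main source. The Migratory maturation list without Cd40 moved by at most 0.131 of the Cd40 shift. In spleen it did move with Cd40, by a median of 0.24 (bootstrap interval 0.13 to 0.35) against 1.85 for Cd40. In lymph node it moved by 0.009 (interval -0.13 to 0.06) against 1.91. These intervals resampled genes that vary together, so a smaller part of maturation in spleen stays open. An exchange of genotype labels between the replicate 3 arrays may be the cause and stays open. Exchanging number 3 in both tissues, without Cd40, gave 4 called genes against 0 as given and 4 as the highest of the other pair exchanges. As first worded this argued against an exchange. But exchanging numbers 1 and 2 in lymph node makes the same split as exchanging 3, so a tie follows from the design. Every exchange that called any gene, 2 to 4 of them, made this lymph node split. All the others called 0 genes, and none called a gene in spleen. With so few genes called, this leaves an exchange open. The pair 3 differences correlated across genes with those of pairs 1 and 2 at 0.00672 and 0.141 in spleen, where pairs 1 and 2 correlated at 0.170 and neither value was negative as an exchange would predict, but at -0.000412 and -0.0105 in lymph node, where pairs 1 and 2 themselves correlated at only -0.0393, so the correlations do not settle it for both tissues.

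Migratory maturation genes were lower on the spleen arrays labelled Cre. A single array is argued against as the only source, since the list median stayed at -0.14 or below without each spleen array in turn. The weakest was without spleen Cre replicate 2 (95% bootstrap interval -0.23 to -0.07). The bootstrap intervals given here resampled genes, not arrays. They treat genes that vary together as independent and do not measure the spread between samples. An exchange of the replicate 3 labels would not make the list lower in pairs 1 and 2, which it leaves as they are, at medians of -0.29 and -0.42, so it is not the cause here, while the pair 3 median of -0.0683 (interval -0.17 to -0.01) leaves open whether those labels were exchanged. A smaller share of mature cells in the spleen sorts labelled Cre may account for it: the 100 genes outside all lists that were highest in migratory cells had a median of -0.11 in the same comparison (interval -0.14 to -0.07). This remains a hypothesis found and tested on the same arrays, and an effect of genotype on maturation itself stays open and untested.

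The replicate 1 arrays of all 4 groups stood apart on the second principal component. A large admixture of another cell type is argued against for 8 marker lists, which left out cDC2 and skin cells. The highest, NK cells, rose by a median of at least 0.16 in every group, below the 0.5 set beforehand. T cells, pDC, Macrophages and monocytes, Neutrophils and Stromal and endothelial cells were also slightly higher in all 4 groups, while B cells and Erythroid cells were not. The Sex-linked list, mostly Y-linked genes that should be silent, was higher in all 4 groups too, by medians of 0.07 to 0.17. So were the dimmest genes, as given below. Such slight rises therefore do not tell a small admixture from a lift of dim genes, and a small admixture stays open. Different handling before or during the sort may contribute: the Immediate early and dissociation stress list, chosen after its values were seen, was lower on replicate 1 in all 4 groups, by medians of -0.30 to -0.52. Other lists also moved 1 way in all 4 groups. Oxidative phosphorylation was higher by 0.35 to 0.49 and Ribosomal proteins by 0.13 to 0.25, while NF-kB pathway was lower, at -0.15 to -0.58. The shift of the stress list therefore does not single out handling. A compressed signal range stays open: the dimmest genes were higher (medians 0.09 to 0.14) and the brightest lower (-0.05 to -0.20) on replicate 1 in all 4 groups, as it would need, but a line in mean level took up only 4.28% to 12.2% of the variance of the deviations, and RMA equalises the arrays' distributions beforehand. The labels give no sort or hybridization date, and differences between the mice stay open and untested.

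Other splits of the arrays were compared with the real counts of called genes. For the tissue comparisons 1 of 10 splits each gave as many genes as the real 5207 and 5648 (highest other 0 in both), and 10 splits are too few for a share under 0.05. For the 4 genotype comparisons the real count was 0, which every split reaches, so 10 of 10 in spleen (highest other 0), 10 of 10 in lymph node (highest other 1) and 100 of 100 drawn splits for the average and for the difference between tissues (highest other 3197 in both) follow from the count itself and decide nothing. The 3 and 4 splits with very many genes all put both replicate 1 arrays of each tissue on the same side, which points to the replicate 1 structure. Among the 16 splits that part as many pairs as the real one, the highest other was 1 in both.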

How the results depend on the processing

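Leaving out all arrays of 1 number, and the block without replicate 3, were chosen after seeing the data. Under the alternatives tried, the 2 tissue comparisons kept Cd40 higher and Xcr1 lower throughout, with Cd40 between 1.93 and 2.43 (control) and between 1.99 and 2.75 (Cre) and Xcr1 between -3.81 and -3.56 and between -3.81 and -3.40 when arrays were left out. The replicate block gave 7178 and 8170 called genes in the tissue comparisons and 0 in the 4 genotype comparisons, and beyond the list calls given in the report it changed no call of a list. Array weights gave 9020 genes for migratory against splenic cDC1 in control mice and 8933 for migratory against splenic cDC1 in Cre mice, 51 in spleen, 2 in lymph node and 3 for the difference between tissues, and turned Xcr1 in that difference to -0.14. The 2-fold threshold gave 2316 and 2369 by construction. The block without replicate 3 gave 1 gene in lymph node, Csf1 at -1.61 (limma adjusted p = 0.0376, against 0 genes called by limma in the other alternatives for lymph node except array weights), with 2 arrays per group. Xcr1 in lymph node turned to 0.0302 with repeated quantile normalization and 0.0202 with the block without replicate 3. The cause was not tested for these.

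When arrays were left out, the count of called genes ran from 2865 to 6906 (control) and from 3081 to 7684 (Cre). Cd40 in the genotype comparisons ran from -0.97 to 0.12 in spleen, from -0.79 to 0.27 in lymph node, from -0.88 to 0.19 averaged and from -0.22 to 0.54 for the difference; Xcr1 ran from -0.33 to 0.0700, from -0.18 to 0.0645, from -0.19 to 0.0163 and from -0.11 to 0.31. Tnfaip3 in lymph node ran from -0.49 to 0.0234. The number of called lists ran from 2 to 7 in spleen, 0 to 7 in lymph node, 0 to 9 averaged, 0 to 6 for the difference, 12 to 18 for tissue among arrays labelled control and 13 to 15 among those labelled Cre. With an estimated correlation camera called 0 lists in each of the 6 comparisons, and fry called 0 in the 4 genotype comparisons, while camera with the replicate block called 3 in lymph node and camera on genes above the median level called 0 in lymph node, 10 in tissue among arrays labelled control and 8 among those labelled Cre. For the single genes named in the report, 45 calls were lost and 17 gained over all alternatives, with no called gene reversed. A dim gene is limited by its signal over the background of 22.2. A fit with inferred sex was not run, since all 12 arrays looked female.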

Other observations

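Some genes of lymph node cDC1, singled out after their values were seen, varied by replicate number there as Cd40 did. In spleen none of these genes followed Cd40 for every replicate number. Csf1, the macrophage growth factor, had intensities of 1178, 990 and 428 on the lymph node arrays labelled control and 317, 396 and 1218 on those labelled Cre, for replicates 1, 2 and 3. Ptgs2, the prostaglandin synthase COX-2, had Cre to control ratios of 0.554, 0.404 and 1.63, Ebi3, the shared subunit of IL-27 and IL-35, had 0.570, 0.560 and 1.88, and Layn, a hyaluronan receptor, had 0.529, 0.651 and 1.56. In spleen Csf1 was low, between 57.5 and 67.2 on all 6 arrays, and the ratios were 0.696, 1.03 and 1.23 for Ptgs2, 1.22, 1.20 and 0.907 for Ebi3, and 1.05, 0.836 and 0.987 for Layn.

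Rnase6, an antimicrobial ribonuclease, also singled out after its values were seen, was higher on the array labelled Cre in each of the 6 same-numbered pairs, with ratios of 1.24, 1.32 and 1.16 in spleen and 1.34, 1.34 and 1.19 in lymph node. Across all genes, the genotype differences of spleen and lymph node correlated at r = -0.0239, a correlation across genes. On the replicate 1 arrays of all 4 groups, Tagap was lower by a mean of -1.81, Rasgef1b by -1.75 and Apol7c by -1.43, and Ly96 was higher by 1.45, on the log2 scale. The Oxidative phosphorylation list was higher there by medians of 0.35 to 0.49, and the NF-kB pathway list was lower by medians of -0.15 to -0.58.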
